A study of Rattus norvegicus with 12 samples.

How the data were processed

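The study measured RNA by sequencing in lung tissue and in endothelial cells (ECs) of Sprague-Dawley rats, in 4 groups of 3 libraries: wild-type (WT) lung in normoxia, WT lung at day 4 of SuHx, lung labelled Ahr-KO at day 4 of SuHx, and WT ECs in normoxia. RNA was extracted with Trizol and a column kit with DNase, and libraries were made by standard Illumina protocols, per the labels. The labels name the rn6 genome build and FastQC, without versions. The aligner, the counter, the normalization and the strand of the libraries are not given in the sources used here. Each sample was assigned to its group by the column names of the table, which carry the group and a suffix from 0 to 2. Since the sample titles number their replicates otherwise, no column was tied to a single sample, and libraries are named here by group and suffix. What the replicates are (animals or repeated preparations) is not stated, so the p-values measure the spread between samples.

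The unit of the deposited values is a signal: the authors gave estimated read counts divided by 1 factor per library. This was read from the values themselves. Low values in a library are multiples of 1 step, which makes 1 read worth 0.745 to 1.25, and 80.9% to 81.8% of the values above 0 lie within 0.05 of a whole number of reads. The rest are fractions, as after an estimate that shares reads between genes. Table totals are 20.6 M to 27.1 M per library, and dividing by the step gives 20.04 M to 28.6 M reads. Of the 19230 rows, 2538 are 0 in all libraries and 1046 name more than 1 gene, so that a change in such a row cannot be given to 1 of its genes. Related and overlapping genes, and genes on opposite strands, may share reads, so their values are uncertain. A value listed at 0 is not read as absence. All 12 sample columns were used.

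Choices of test were made before the data were examined, for several possible units: a count model for whole counts, and limma for scaled values. The values were scaled and not whole, so limma was used. Genes with a mean signal of at least 1 over the fitted libraries were tested on log2(signal + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend, group means, two-sided). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 3 lung comparisons came from 1 fit of the 9 lung libraries, and ECs were compared with normoxia lung in a fit of those 6 libraries. Fold changes are ratios of geometric means of the signal plus 1. No genotype by treatment interaction could be fitted, since the table holds no Ahr-KO normoxia group.

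There were 25 gene lists of pathways and cell type markers, with 430 members. Of these, 398 matched a row by symbol, 28 in a row that merges genes, 1 by a synonym and 3 not at all. Each list with at least 3 tested members was compared with the other genes by limma's camera, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 25 lists within a comparison. It was tested again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. Members were counted over all tested genes and adjusted over the list alone. Genes were named by a rule. It took the 10 largest called changes in each direction among genes with a mean of at least 1 over both groups, without overlap between the libraries of the groups (chance gives 10% of genes no overlap for 3 against 3) and with a symbol not starting with LOC, RGD, AABR, AC0, ENSRNOG or Mt-. It added Ahr and all measured AhR targets, and for each list described up to 4 called members with the smallest adjusted p, or the 2 with the highest mean where none was called. A few genes that the rule takes are not reported here. A gene named outside this rule is marked as chosen after its values were seen.

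Overlaps of calls between comparisons that share libraries were set beside independent lists and beside 100 simulations. In these, all lung libraries were drawn around 1 mean per gene, so no gene differed, while the comparisons still shared libraries. Almost no gene is called where none changes. Such simulations therefore cannot give the overlap of calls to be had by chance where many genes change. Alternatives planned were limma without its trend, quantile normalization, no filter or a mean of at least 5, an absolute log2 fold change of at least 1, all 12 libraries or only the groups compared in the fit, a pseudocount of 0.1, the suffix of the columns as a replicate block, and each library left out in turn. Where a gene is said to lose its call in a number of alternatives, the block is not among them. Added after the data had been seen were leaving out both libraries with much cardiac or airway RNA (normoxia 2 and Ahr-KO 2), the mean log2 level of the cardiac markers as a covariate, and setting to missing a value under 1 in any library whose group had at least 50 in both others. Neighbourhood of genes was read from the gene order of the GRCr8 assembly, another build than rn6, by symbol alone, which placed 14979 of the 15234 tested genes. No coordinates are given. Explanations for 3 further results (Rpl39, Ly6al and the VEGF pathway genes) were tested once as well and are not weighed here, to keep the weighing to 3 patterns.

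The fits were tested on simulated data drawn with the means, depth and spread of these libraries. The changed genes had a mean signal of at least 20. Of 100 genes changed 2-fold, 67 were called in the simulated WT SuHx comparison, 68 in that of the SuHx groups and 61 in that of ECs and lung, and of 100 genes changed 4-fold 94, 88 and 89. Among the 15235, 15228 and 15153 genes tested there, 9, 8 and 9 unchanged ones were called, and of 200 unchanged lists 2, 8 and 5 had a camera p under 0.05. No library was a copy of another, since the mean chi-square per gene was 6.16 to 24.5 in the 12 pairs within groups, where counting error alone gives 1. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1, so none was used for single genes.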

Results

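RNA from rat lung was sequenced in 4 groups of 3 libraries, all from Sprague-Dawley rats. Total lung was taken from wild-type (WT) rats in normoxia at day 0, from WT rats at day 4 of SuHx, and from rats labelled Ahr-KO at day 4 of SuHx. SuHx combines SU5416 (Sugen), an inhibitor of the VEGF receptors, with hypoxia, and is a model of pulmonary arterial hypertension. No group received SU5416 or hypoxia alone, so a change with SuHx cannot be given to the drug, the hypoxia or the disease. Ahr encodes the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor. The fourth group held endothelial cells (ECs) from WT rats in normoxia. Its day is labelled 4, while its column names give 0. The deposited table gave 19230 rows of gene symbols, each with 1 signal per library, an estimated read count divided by 1 factor for that library. Its totals lay between 20.6 M and 27.1 M per library, which stood for 20.04 M to 28.6 M reads. Along the first principal component, with 71.2% of the variance, the ECs (109 to 119.8) lay apart from all lung libraries (-58.7 to -24.7). The second component, with 9.89%, separated the normoxia lungs (-55.9 to -21.7) from the SuHx lungs (7.99 to 31.7). On the third, with 5.97%, the WT SuHx libraries lay between 21.5 and 36.6 and those labelled Ahr-KO between -35.5 and -14.5, with normoxia replicate 2 at -16.5. Values are mean signal ± SD over the 3 libraries of a group, and log2 fold changes are given ± their standard error.

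Ahr was measured in every library. Its signal was 5565, 3103 and 3950.3 in the normoxia lungs (4206 ± 1251), 1996, 3073 and 1739.6 in the WT SuHx lungs (2269.6 ± 708), and 2515, 2523 and 1800.0 in the SuHx lungs labelled Ahr-KO (2279 ± 415). The ECs gave 5697, 4767 and 6086. Ahr mRNA was thus not lower in the lungs labelled Ahr-KO than in the WT SuHx lungs (log2 fold change 0.03 ± 0.26, adjusted p = 0.966). The deleted part of the gene is not given in the sources used here, so a value for the whole gene may check nothing, and the genotype is given below as labelled. Both SuHx groups lay below normoxia: Ahr fell with SuHx in WT lung (log2 fold change -0.89 ± 0.26, adjusted p = 0.0495) and was not called in the lungs labelled Ahr-KO (log2 fold change -0.86 ± 0.26, adjusted p = 0.0676). The WT call was lost in 10 of 16 alternative settings, in which its adjusted p reached 0.157.

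**Figure D1:**
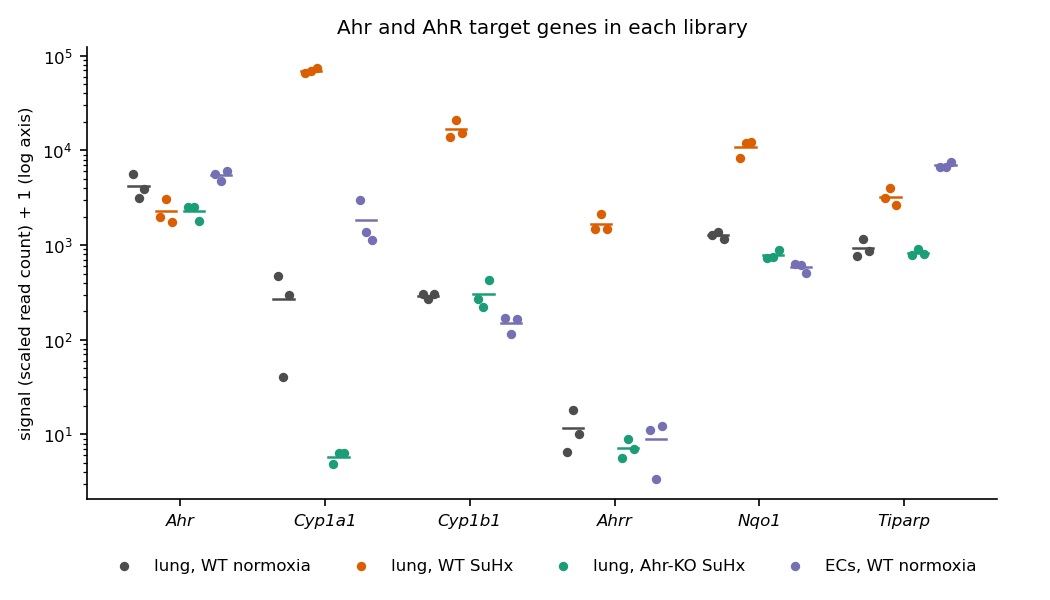
Signal of Ahr and of 5 AhR target genes in each library (points, log10 axis of the signal plus 1) with group means (bars), n = 3 per group. Ahr lay between 1739.6 and 6086 in all 12 libraries, while Cyp1a1 lay between 65459 and 75070.5 in the WT SuHx lungs and between 3.87 and 5.32 in the SuHx lungs labelled Ahr-KO.

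WT SuHx lung was set against WT normoxia lung to find what SuHx changed by day 4. AhR target genes gave the largest rises. Cyp1a1, a cytochrome P450 that oxidises polycyclic aromatic hydrocarbons, went from 271 ± 219.5 in normoxia to 69806 ± 4871, a 389-fold rise (log2 fold change 8.60 ± 0.72). Ahrr, the repressor of AhR, rose 156-fold, Cyp1b1 56.2-fold, the quinone reductase gene Nqo1 8.50-fold, and Tiparp, an ADP-ribosyltransferase gene, 3.51-fold. Of the 10 tested AhR target genes, 7 rose, 1 fell and 2 were not called (adjusted over the list alone, 8 and 1). The list rose against the other genes (median log2 fold change 1.95, adjusted p = 8.50e-09, and adjusted p = 0.0606 with an estimated correlation). The row that merges Ugt1a6 with its neighbours rose 3.22-fold and the amino acid transporter gene Slc7a5 2.00-fold. Xdh, xanthine dehydrogenase, was the member that fell (log2 fold change -0.94 ± 0.16, adjusted p = 0.00650). Cyp1a2 (log2 fold change 2.09 ± 0.78, adjusted p = 0.104) and Aldh3a1 (log2 fold change 0.81 ± 0.45, adjusted p = 0.244) were not called.

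Other large rises were those of Stk32b, a serine/threonine kinase gene (124-fold), the blood group gene Kel (26.5-fold), Lypd1 (22.2-fold), the short-chain fatty acid receptor gene Ffar3 (21.1-fold), Ntrk2, which encodes a BDNF receptor (19.8-fold), and the merged row of Fam64a and Pimreg (17.3-fold). Cacng3 was listed at 0 in all SuHx lungs and at 21.5, 13.6 and 11.5 in normoxia. Falls were largest for Dgcr2 (23.1-fold lower), Igip (22.7-fold), the merged row of the drug efflux transporters Abcb1a and Abcb1b (15.1-fold), Unc5d (11.5-fold), the Notch ligand Dll4 (9.95-fold), Slc24a2 (9.11-fold), Cyp2a3 (9.04-fold), Zbtb16 (8.99-fold) and Col6a4 (8.85-fold). Zbtb16 was at 554, 7138 and 3778 in the normoxia lungs against 276 ± 48.5 in WT SuHx, so its fold depends on the libraries used. The call of Igip (adjusted p = 0.0471) was lost in 10 of 16 alternatives, in which its adjusted p reached 0.147.

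Cell cycle, matrix and red cell genes rose as groups. Of the 31 tested cell cycle genes, 27 rose, 0 fell and 4 were not called (adjusted over the list alone, 29 and 0). Mcm5, a part of the replicative helicase, rose 4.76-fold, Mcm6 2.96-fold, the mitotic checkpoint gene Bub1 3.28-fold and cyclin Ccna2 2.88-fold, and the list passed (median log2 fold change 1.72, adjusted p = 2.13e-22, and adjusted p = 0.148 with an estimated correlation). Of the 27 tested extracellular matrix and remodelling genes, 17 rose, 0 fell and 10 were not called (adjusted over the list alone, 23 and 0), which included elastin (Eln, 11.4-fold), the crosslinking enzyme Loxl2 (2.36-fold) and Col5a1 (1.80-fold). Eln varied widely between the normoxia lungs (16692 ± 11662), so its fold depends on the libraries used. The matrix list passed as well (median log2 fold change 0.85, adjusted p = 1.20e-12, and adjusted p = 0.148 with an estimated correlation). All 9 tested erythroid cell markers rose, also adjusted over the list alone, among them Slc4a1 (13.2-fold), Ahsp (12.8-fold), Epb42 (5.29-fold) and the haem synthesis gene Alas2 (5.06-fold). The erythroid list passed (median log2 fold change 2.40, adjusted p = 8.62e-09, and adjusted p = 0.307 with an estimated correlation). Globin rows took 0.278% to 0.387% of the signal in the normoxia lungs and 0.960% to 1.91% in the WT SuHx lungs.

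Some markers of neutrophils and of the mesenchyme rose too. Of the 13 tested neutrophil markers, 2 rose, 0 fell and 11 were not called (adjusted over the list alone, 3 and 0), with Il1r2 (5.64-fold) and Lcn2 (4.68-fold) as the called ones (list: median log2 fold change 1.39, adjusted p = 0.00371, and adjusted p = 0.529 with an estimated correlation). Of the 14 tested smooth muscle and pericyte markers, 5 rose, 1 fell and 8 were not called (adjusted over the list alone, 6 and 1). The contractile genes Des (2.90-fold), Cnn1 (2.49-fold) and Tagln (2.29-fold) rose, whereas Rgs5, a pericyte gene, fell 2.19-fold (list: median log2 fold change 0.56, adjusted p = 0.00722, and adjusted p = 0.620 with an estimated correlation). Of the 12 tested fibroblast markers, 3 rose, 0 fell and 9 were not called (adjusted over the list alone, 3 and 0): Lum (2.72-fold), Meox1 (2.43-fold) and Dpt (1.45-fold). The fibroblast list passed (median log2 fold change 0.32, adjusted p = 0.0309, and adjusted p = 0.529 with an estimated correlation). Of the 26 tested cytokines, chemokines and adhesion molecules, 5 rose, 0 fell and 21 were not called (adjusted over the list alone, 5 and 0), among them the chemokines Cxcl10 (7.56-fold), Cxcl11 (5.87-fold) and Ccl2 (5.58-fold) and the adhesion molecule Vcam1 (1.53-fold). The cytokine list passed (median log2 fold change 0.28, adjusted p = 0.00952, and adjusted p = 0.307 with an estimated correlation). Of the 12 tested NRF2 target genes, 4 rose, 0 fell and 8 were not called (adjusted over the list alone, 4 and 0), with Srxn1 (3.96-fold), the haem oxygenase Hmox1 (2.01-fold), Me1 (1.46-fold) and Txnrd1 (1.27-fold). The NRF2 list passed (median log2 fold change 0.34, adjusted p = 0.00619, and adjusted p = 0.307 with an estimated correlation).

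Genes of VEGF and BMP signalling fell on balance. Of the 20 tested VEGF pathway and endothelial tip cell genes, 2 rose, 8 fell and 10 were not called (adjusted over the list alone, 3 and 9). Dll4 and the tip cell gene Esm1 (6.74-fold lower) fell most, Plvap fell 2.16-fold, and the ligand Vegfc rose 1.99-fold (list: median log2 fold change -0.36, adjusted p = 0.0309, and adjusted p = 0.529 with an estimated correlation). Of the 28 tested BMP signalling and pulmonary hypertension genes, 2 rose, 9 fell and 17 were not called (adjusted over the list alone, 2 and 11). The inhibitory Smad6 fell 4.57-fold, Tmem100 3.62-fold, the serotonin transporter Slc6a4 2.84-fold and the TGF-beta co-receptor Eng 2.34-fold (list: median log2 fold change -0.26, adjusted p = 0.00806, and adjusted p = 0.529 with an estimated correlation). Of the 20 tested endothelial cell markers, 2 rose, 6 fell and 12 were not called (adjusted over the list alone, 3 and 8): Clec14a (2.86-fold), the row of Lyve1 (2.61-fold) and Car4 (1.59-fold) fell while Emcn rose 2.08-fold, and the list as a whole did not pass (median log2 fold change -0.22, adjusted p = 0.331, and adjusted p = 0.772 with an estimated correlation). Of the 16 tested alveolar epithelial markers, 0 rose, 2 fell and 14 were not called (adjusted over the list alone, 0 and 2): Rtkn2 (2.10-fold) and Slc34a2 (1.62-fold). The alveolar list passed (median log2 fold change -0.32, adjusted p = 0.00619, and adjusted p = 0.620 with an estimated correlation).

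Among the remaining lists none passed with camera, and fry called 1 of them, the monocyte and macrophage markers (adjusted p = 0.0254). Of the 26 tested hypoxia-induced genes, 7 rose, 2 fell and 17 were not called (adjusted over the list alone, 7 and 3): the glycolytic genes Ldha (1.61-fold), Eno1 (1.59-fold) and Aldoa (1.48-fold) rose and Mxi1, a MYC antagonist, fell 1.38-fold (list adjusted p = 0.224). For the monocyte and macrophage markers (adjusted p = 0.191) the counts were 3 higher, 0 lower and 13 not called, or 3 and 0 adjusted over the list alone, the 3 called being the complement genes C1qb (3.60-fold), C1qa (3.32-fold) and C1qc (3.04-fold). Interferon-stimulated genes gave 2 higher, 0 lower and 15 not called, or 2 and 0 adjusted over the list alone (adjusted p = 0.191), with Ifit1 16.3-fold and Rsad2 2.57-fold higher. Glucocorticoid-induced genes gave 3 higher, 2 lower and 6 not called, or 4 and 2 adjusted over the list alone (adjusted p = 0.318), with Mt2A 3.73-fold and Sgk1 1.51-fold higher and Zbtb16 and Errfi1 lower. Immediate early and heat shock genes gave 2 higher, 0 lower and 16 not called, or 2 and 0 adjusted over the list alone (adjusted p = 0.626), Ier3 and Dnajb1 being the called ones. Mast cell markers gave 0 higher, 1 lower and 7 not called, or 0 and 1 adjusted over the list alone (adjusted p = 0.950), with Kit 2.05-fold lower. Airway epithelial markers gave 0 higher, 1 lower and 14 not called, or 0 and 1 adjusted over the list alone (adjusted p = 0.245), with Sec14l3 2.34-fold lower. No member was called, over all genes or adjusted over the list alone, among the circadian clock genes (adjusted p = 0.427), T and NK cell markers (0.661), B and plasma cell markers (0.427), mesothelial markers (0.427) and cardiac muscle markers (0.224, median log2 fold change -1.51), and examples with their values were Tef (-0.70 ± 0.42), Cd4 (-0.40 ± 0.26), Xbp1 (-0.02 ± 0.10), Krt19 (-0.55 ± 0.20) and Actc1 (1.29 ± 0.72). Median and mean differed in sign for the glucocorticoid-induced genes (0.05 and -0.00116, tested upward) and the mast cell markers (0.05 and -0.0262, tested downward).

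In all, limma called 2052 of the 15234 tested genes for WT SuHx against WT normoxia, 1079 higher and 973 lower, of which 493 and 255 changed at least 2-fold. The count was 953 without normoxia replicate 0, 1148 without normoxia replicate 1, 862 without WT SuHx replicate 0 and 1115 without WT SuHx replicate 2, so single libraries moved it by over 1.5 times. Of the 12 lists that passed, none held with an estimated correlation, fry lost the smooth muscle (0.105), fibroblast (0.106) and alveolar calls (0.105), and leaving out 1 library lost the call of VEGF (normoxia 2, 0.0838; WT SuHx 2, 0.0502), smooth muscle (WT SuHx 1, 0.0653), fibroblast (normoxia 1, 0.125; WT SuHx 0, 0.092) and alveolar genes (normoxia 1, 0.066; WT SuHx 1, 0.0653).

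**Figure D2:**
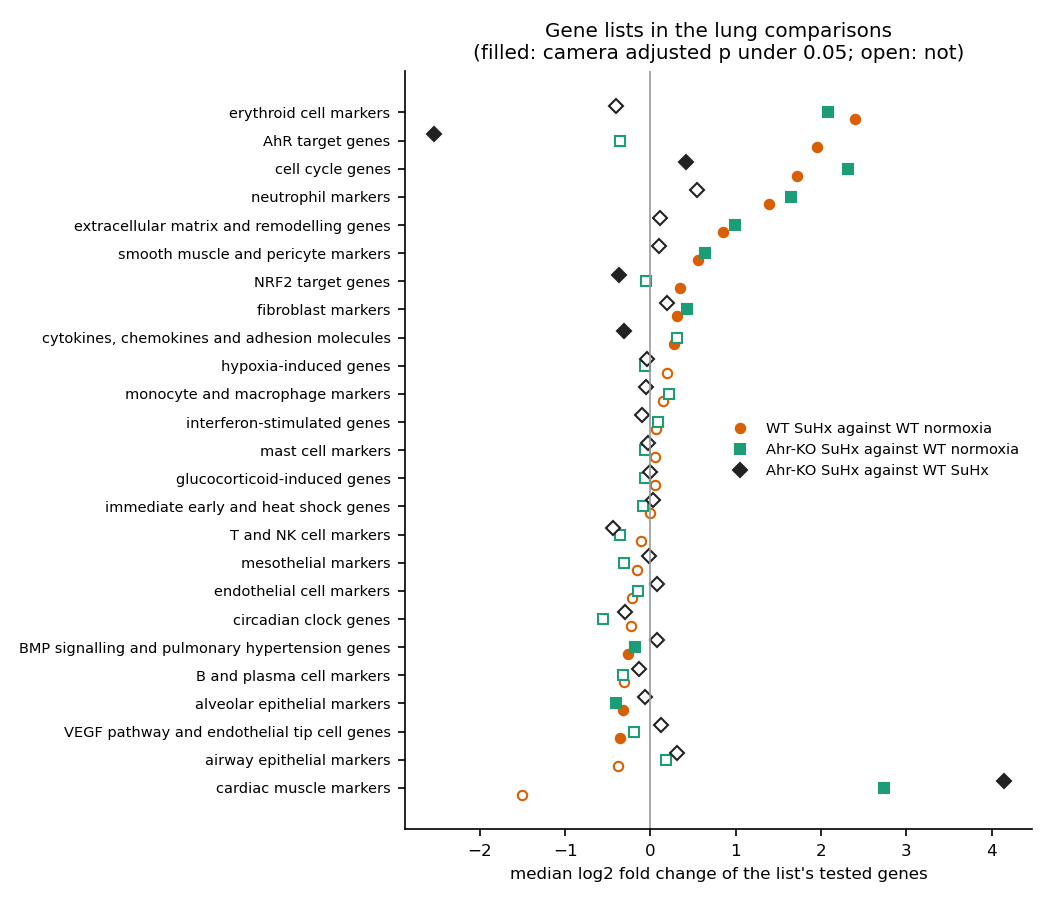
Median log2 fold change of the tested members of each of the 25 gene lists (x axis) in the 3 lung comparisons, filled where camera's adjusted p was under 0.05. Cell cycle genes had medians of 1.72 and 2.31 in the SuHx lungs of both genotypes against normoxia, while AhR target genes had 1.95 in WT and -0.36 in the lungs labelled Ahr-KO.

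The SuHx lungs labelled Ahr-KO were set against the WT SuHx lungs to find which genes differed with genotype under the same treatment. AhR target genes were again among the most different. Cyp1a1 was at 4.83 ± 0.835 in the lungs labelled Ahr-KO against 69806 ± 4871 in WT (log2 fold change -13.55 ± 0.72, adjusted p = 2.08e-05). Ahrr was 234-fold lower, Cyp1b1 56.1-fold, Nqo1 13.7-fold, Aldh3a1 8.10-fold, Tiparp 3.85-fold and the merged Ugt1a6 row 2.95-fold. Of the 10 tested AhR target genes, 0 were higher, 7 were lower and 3 were not called (adjusted over the list alone, 0 and 8). The list was lower and held with either correlation (median log2 fold change -2.54, adjusted p = 5.32e-17, and adjusted p = 0.00918 with an estimated correlation). Values of the members not called were -2.06 ± 0.78 for Cyp1a2, -0.13 ± 0.16 for Xdh and 0.12 ± 0.13 for Slc7a5. Since Ahr mRNA was not lower, these directions rest on the genotype as labelled.

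Further genes lower in the lungs labelled Ahr-KO were Stk32b (283-fold), Mfrp (9.21-fold), the desmosomal plakophilin Pkp1 (8.58-fold), Ms4a7 (7.71-fold) and Cytl1 (7.67-fold). Higher there were Ly6al (731 ± 262 against 5.88 ± 2.90, 108-fold), the ribosomal protein gene Rpl39 (10.6-fold), the merged row of ribosomal RNA (7.20-fold), the ligand Bmp2 (5.40-fold), Cacna2d4 (4.82-fold), Lrrc3b (4.43-fold), Bean1 (3.11-fold), Grin2c (3.07-fold) and Ano5 (2.92-fold). Slc5a5, the iodide transporter, was listed at 0 in all WT SuHx lungs and at 4.64, 7.97 and 5.32 in those labelled Ahr-KO. The ribosomal RNA row lay between 3007 and 4398 in the lungs labelled Ahr-KO, between 198 and 848 in the WT lungs of both treatments, and between 1563 and 2031 in the ECs. No label gives a preparation batch, so for this row a difference in preparation cannot be told apart from one of the labelled genotype. In the ECs, which are WT, Rpl39 varied 11.7-fold between libraries, at 93.4, 105 and 1098. The highest of these came close to the lungs labelled Ahr-KO (1347 to 1682).

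A few genes of BMP and VEGF signalling were called. Of the 28 tested BMP signalling and pulmonary hypertension genes, 2 were higher, 2 were lower and 24 were not called (adjusted over the list alone, 4 and 2). Beside Bmp2, Smad6 was 1.62-fold higher, while the vasoconstrictor endothelin 1 (Edn1, 3.23-fold) and the BMP receptor Acvrl1 (2.12-fold) were lower, and the list did not pass (median log2 fold change 0.08, adjusted p = 0.311, and adjusted p = 0.871 with an estimated correlation). Of the 20 tested VEGF pathway and endothelial tip cell genes, 1 was higher, 0 were lower and 19 were not called (adjusted over the list alone, 3 and 1), the called one being Dll4 (2.37-fold higher; list: median log2 fold change 0.12, adjusted p = 0.311, and adjusted p = 0.871 with an estimated correlation). Among the neutrophil markers Il1r2, the decoy receptor of IL-1, was 2.76-fold lower (0 higher, 1 lower and 12 not called, or 0 and 1 adjusted over the list alone), and among the monocyte and macrophage markers C1qc was 1.96-fold lower (0 higher, 1 lower and 15 not called, or 1 and 3 adjusted over the list alone). Neither of these lists passed (adjusted p = 0.650 and 0.332).

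No member of the NRF2 target list was called, and 7 were lower adjusted over the list alone (list: median log2 fold change -0.37, adjusted p = 4.74e-06, and adjusted p = 0.158 with an estimated correlation). Its most abundant members, Taldo1 (-0.28 ± 0.15) and Pgd (-0.45 ± 0.14), were not called. None of the 31 rows of the cell cycle list was called, over all genes or adjusted over the list alone, while as a list they were higher (list: median log2 fold change 0.42, adjusted p = 0.000166, and adjusted p = 0.871 with an estimated correlation), as in Mki67 (log2 fold change 0.59 ± 0.23, adjusted p = 0.307). Outside those 31, a merged row of the list member Foxm1 with Nrip2, chosen after its values were seen, was called higher (log2 fold change 0.79 ± 0.14, limma's adjusted p = 0.0480). The cytokine list, with no call over all genes and 3 lower adjusted over the list alone, was lower (median log2 fold change -0.31, adjusted p = 0.0330, and adjusted p = 0.737 with an estimated correlation), as in Icam1 (-0.42 ± 0.14) and Il33 (-0.55 ± 0.20). The cell cycle call was lost with fry (adjusted p = 0.486). The cytokine call was lost with fry (0.286), without WT SuHx replicate 1 (0.144) and without Ahr-KO replicate 2 (0.0908). The other 16 lists did not pass and had no member called over all genes. Adjusted over the list alone, 1 hypoxia-induced gene was higher and 2 lower, 2 immediate early genes were higher and 2 lower, 1 endothelial marker was lower and 1 mast cell marker higher. Median, mean and test differed in sign for the glucocorticoid-induced genes (-0.00 and 0.204, tested upward), the immediate early genes (0.04 and 0.0291, tested downward), and the monocyte (-0.05 and 0.0225, tested downward) and mast cell markers (-0.03 and 0.0736, tested downward).

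Markers of other tissue differed between the same groups. As a list, cardiac muscle markers were higher in the lungs labelled Ahr-KO (median log2 fold change 4.14, adjusted p = 5.38e-07, and adjusted p = 0.871 with an estimated correlation), although none of the 14 was called over all genes and 10 were higher adjusted over the list alone. Myh6, the atrial myosin heavy chain, was at 1228, 673 and 4900.1 in the lungs labelled Ahr-KO and listed at 0 in all WT SuHx lungs. In normoxia it was at 4.77, 0 and 2879.7, so replicate 2 of that group carried it too. Actc1 was high in every lung library, from 267 upward. So was the merged row of Dnaaf3 and Tnni3, from 476, which cannot be given to Tnni3 alone. Rat pulmonary veins are known to carry sleeves of cardiac muscle, and 8 of the 14 cardiac markers were above 0 in every lung library. Yet Myl7, like Myh6, was near 0 in the WT SuHx lungs (at most 0.745). Actc1 and the merged row thus do not by themselves show cardiac muscle in every lung. Ahr-KO replicate 2 stood apart further, with the airway gene Bpifa1 at 28979.8 against at most 1231 in other lung libraries, and 5 mitochondrial rows, COX1 among them, listed at 0. The airway list did not pass (adjusted p = 0.0553), and the call of the cardiac list was lost with fry (adjusted p = 0.286).

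**Figure D3:**
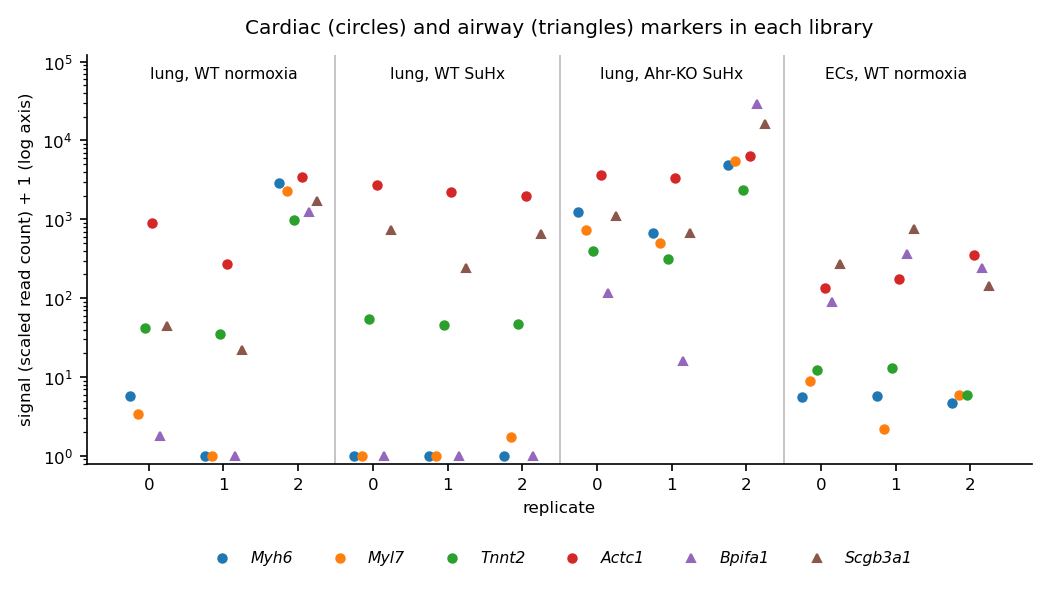
Signal of 4 cardiac genes and 2 airway genes in each library (points, log10 axis of the signal plus 1), n = 3 per group. Myh6 reached 2879.7 in normoxia replicate 2 and lay between 673 and 4900.1 in the lungs labelled Ahr-KO, while all WT SuHx lungs were listed at 0.

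For Ahr-KO SuHx against WT SuHx, limma called 76 of the 15234 tested genes, 30 higher and 46 lower, and 2078 genes had an unadjusted p under 0.05. The count was 32, 39 and 39 without WT SuHx replicates 0, 1 and 2, 37 without Ahr-KO replicate 0 and 35 without Ahr-KO replicate 1, and it was 19 with a cardiac score as a covariate. Of the 28 called genes named here, 11 kept the call in all alternatives, among them Cyp1a1, Cyp1b1, Ahrr, Nqo1, Stk32b, Bmp2, Ly6al and Rpl39, and 17 lost it in at least 1, among them Aldh3a1 (7 of 16), Dll4 (5 of 16), Smad6 (8 of 16), Il1r2 (8 of 16) and C1qc (11 of 16).

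SuHx lung labelled Ahr-KO was also set against WT normoxia, which asks which SuHx changes appeared in rats of that label. Both treatment and labelled genotype differ here, since the table holds no Ahr-KO normoxia group. Cell cycle and matrix genes rose, and AhR targets did not rise as a group. Of the 31 tested cell cycle genes, 28 rose, 0 fell and 3 were not called (adjusted over the list alone, 29 and 0), with Birc5 (6.16-fold), Mcm5 (5.09-fold), Bub1 (4.29-fold) and Ccna2 (3.99-fold). The cell cycle list passed (median log2 fold change 2.31, adjusted p = 2.12e-29, and adjusted p = 0.124 with an estimated correlation). Of the 27 tested extracellular matrix and remodelling genes, 16 rose, 0 fell and 11 were not called (adjusted over the list alone, 24 and 0), with Mmp12 (3.90-fold), Loxl2 (3.24-fold) and Col5a1 (1.99-fold). The matrix list passed (median log2 fold change 0.99, adjusted p = 3.76e-14, and adjusted p = 0.124 with an estimated correlation). Of the 10 tested AhR target genes, 1 rose, 4 fell and 5 were not called (adjusted over the list alone, 1 and 4). Cyp1a1 was 30.9-fold lower than in WT normoxia, Aldh3a1 4.63-fold, Xdh 2.10-fold and Nqo1 1.61-fold, Slc7a5 was 2.16-fold higher, and the list did not pass (median log2 fold change -0.36, adjusted p = 0.174, and adjusted p = 0.642 with an estimated correlation). Values of members not called were 0.00 ± 0.23 for Cyp1b1, -0.58 ± 0.37 for Ahrr, -0.13 ± 0.18 for Tiparp, 0.02 ± 0.78 for Cyp1a2 and 0.13 ± 0.11 for the Ugt1a6 row.

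Ly6al (46.3-fold), Fam64a with Pimreg (43.3-fold), Ntrk2 (34.6-fold), Fcrl2 (24.1-fold), Mxd3 (20.3-fold), Kel (18.9-fold), C1qtnf3 (17.8-fold), Thbs4 (17.3-fold) and Ffar3 (16.6-fold) rose most. Reg3b was listed at 0 in normoxia and at 18.6, 14.2 and 305 in the lungs labelled Ahr-KO. Next to Cyp1a1 and Cacng3, the largest falls were those of Nkx2-8 (15.0-fold), Sorcs1 (8.18-fold), Cpne4 (7.72-fold), Olr312 (6.50-fold), Col6a4 (6.30-fold), the VIP receptor gene Vipr1 (6.14-fold), Bank1 (6.12-fold) and Fmo2 (6.12-fold). In Ahr-KO replicates 0, 1 and 2, Thbs4 was at 46.4, 21.3 and 502 and Fcrl2 at 661, 530 and 101, so both folds depend on replicate 2. The calls of Thbs4 and Sorcs1 were lost in 10 of 16 and 8 of 16 alternatives.

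Of the cell type lists, all 9 erythroid markers rose, with Slc4a1 (12.1-fold). Erythroid markers passed as a list (median log2 fold change 2.08, adjusted p = 5.24e-08, and adjusted p = 0.476 with an estimated correlation). Of the 13 tested neutrophil markers, 4 rose, 0 fell and 9 were not called (adjusted over the list alone, 10 and 0), with Camp (5.25-fold) and Lcn2 (3.15-fold). Neutrophil markers passed as a list (median log2 fold change 1.65, adjusted p = 5.17e-05, and adjusted p = 0.476 with an estimated correlation). Of the 14 tested smooth muscle and pericyte markers, 5 rose, 1 fell and 8 were not called (adjusted over the list alone, 6 and 1), with Des (3.10-fold) and Cnn1 (2.33-fold). Smooth muscle markers passed as a list (median log2 fold change 0.64, adjusted p = 0.000431, and adjusted p = 0.642 with an estimated correlation). Of the 12 tested fibroblast markers, 5 rose, 0 fell and 7 were not called (adjusted over the list alone, 6 and 0), with Meox1 (3.05-fold) and the hedgehog target Gli1 (2.00-fold). Fibroblast markers passed as a list (median log2 fold change 0.43, adjusted p = 0.00256, and adjusted p = 0.501 with an estimated correlation). Of the 16 tested alveolar epithelial markers, 0 rose, 1 fell and 15 were not called (adjusted over the list alone, 0 and 5), the called one being Rtkn2 (2.03-fold). Alveolar markers passed as a list (median log2 fold change -0.41, adjusted p = 0.000355, and adjusted p = 0.642 with an estimated correlation). Of the 28 tested BMP signalling and pulmonary hypertension genes, 3 rose, 9 fell and 16 were not called (adjusted over the list alone, 4 and 12). Tmem100 (3.02-fold), Smad6 (2.82-fold) and Edn1 (2.50-fold) fell and Bmp2 rose 4.35-fold (list: median log2 fold change -0.18, adjusted p = 0.0145, and adjusted p = 0.642 with an estimated correlation). Of the 20 tested VEGF pathway and endothelial tip cell genes, 1 rose, 8 fell and 11 were not called (adjusted over the list alone, 4 and 8), with Dll4 (4.20-fold), Esm1 (4.56-fold), Plvap (3.32-fold) and the angiopoietin receptor Tek (2.38-fold) lower, and that list did not pass (median log2 fold change -0.19, adjusted p = 0.256, and adjusted p = 0.737 with an estimated correlation).

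None of the 14 cardiac muscle markers was called, over all genes or adjusted over the list alone, while as a list they were higher in the lungs labelled Ahr-KO (median log2 fold change 2.74, adjusted p = 0.00262, and adjusted p = 0.680 with an estimated correlation). In Actc1 (log2 fold change 2.18 ± 0.72, adjusted p = 0.0910) and Myh6 (log2 fold change 5.97 ± 2.34, adjusted p = 0.145) libraries of both groups differed widely. Actc1 was at 3648, 3346 and 6273 in the lungs labelled Ahr-KO and at 903, 267 and 3389.7 in normoxia, and Myh6 at 1228, 673 and 4900.1 against 4.77, 0 and 2879.7. The other 14 lists did not pass. Median and test, or median and mean, differed in sign for the hypoxia-induced (-0.06 and 0.159), NRF2 target (-0.05 and 0.0205), glucocorticoid-induced (-0.06 and 0.203) and immediate early genes (-0.09 and 0.0376) and the mast cell markers (-0.07 and 0.0473). In this comparison limma called 1485 of 15234 genes, 906 higher and 579 lower. Without normoxia replicates 0 and 1 the count was 795 and 888, without Ahr-KO replicates 0, 1 and 2 it was 976, 721 and 875, and with a cardiac score as a covariate it was 556. Of the 9 lists that passed, none held with an estimated correlation, and fry lost the smooth muscle, fibroblast, alveolar and cardiac calls (adjusted p = 0.0665, 0.0618, 0.0816 and 0.318), while the BMP call was lost with quantile normalization (0.09) and without normoxia replicate 2 (0.0646), and the cardiac call without Ahr-KO replicate 2 (0.093).

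Part of the SuHx response was called in the lungs of both labels. Of the 1079 genes that rose in WT SuHx lung, 617 were also called higher in the SuHx lungs labelled Ahr-KO against the same normoxia libraries, and of the 973 that fell, 350 were called lower, 967 genes or 47.1% together. The share was 28.5% without Ahr-KO replicate 2 and 70.9% without WT SuHx replicate 2. Independent lists would share 64.2 and 37.0 genes. Simulated groups without any change shared 0 in 100 simulations, which says little here, because almost no gene is called where none changes. Across genes, which are not independent replicates, the log2 fold changes had a covariance of 0.286 against 0.0654 in the simulated groups. The 3 normoxia libraries could not be divided between the comparisons, so part of the excess can come from them. Over the 1079 genes the median log2 fold change was 0.89 in WT and 0.73 in the lungs labelled Ahr-KO, with 1029 of the same sign, and over the 973 it was -0.72 and -0.50, with 951 of the same sign. The 0.73 was 1.34 without normoxia replicate 0 and 1.32 without WT SuHx replicate 0. Genes chosen for their call in WT are overestimated there. Genes chosen in the lungs labelled Ahr-KO had medians of 1.17 there and 0.91 in WT (906 higher), and -0.65 and -0.57 (579 lower). The shared count was 541 and 594 without normoxia replicates 0 and 1, 536 without WT SuHx replicate 0 and 542 without Ahr-KO replicate 1.

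Of the genes changed by SuHx in WT, 52 differed in the opposite direction between the SuHx groups. Cyp1a1, Ahrr, Stk32b, Cyp1b1, Nqo1 and Tiparp were among 39 genes that rose with SuHx in WT and were lower in the SuHx lungs labelled Ahr-KO than in WT SuHx. Dll4 and Smad6 were among 13 genes that fell in WT and were higher in the lungs labelled Ahr-KO. Against normoxia, 9 of the 52 were called in the same direction in the lungs labelled Ahr-KO as in WT, 6 in the opposite one, and 37 were not called. Dll4 (log2 fold change -2.07) and Smad6 (-1.50) were among the 9. Both comparisons share the WT SuHx libraries with opposite signs, which by itself favours opposite directions. Independent lists would give 3.26 and 1.92 such genes. Unchanged simulated groups gave 0.01 in the mean and at most 1, which says little, because almost no gene is called where none changes. Across genes the covariance was -0.157 against -0.0656 in the simulated groups. Without normoxia replicate 0 the count of 52 was 28, without WT SuHx replicates 0, 1 and 2 it was 22, 29 and 23, and without Ahr-KO replicates 0 and 1 it was 24 and 22.

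**Figure D4:**
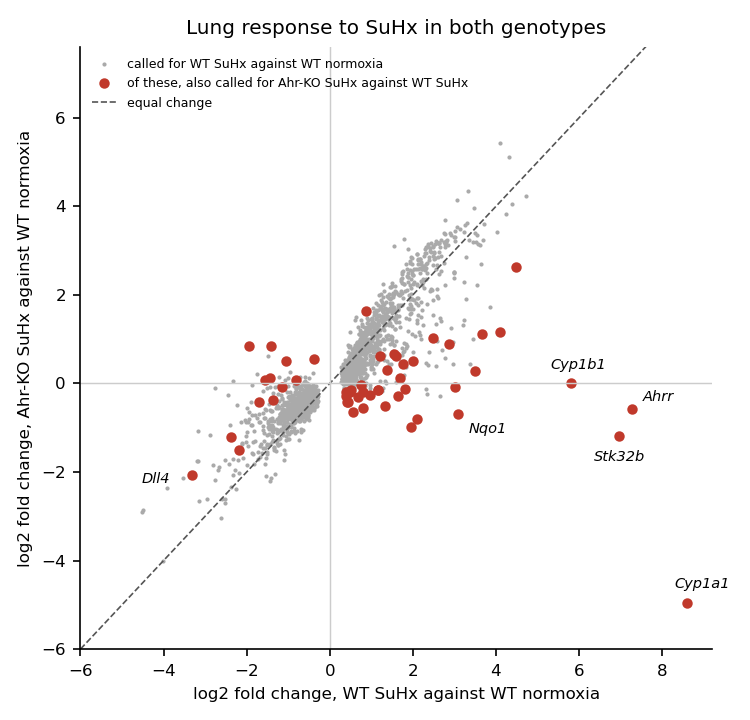
Log2 fold change of the genes called for WT SuHx against WT normoxia, in WT (x axis) and in the SuHx lungs labelled Ahr-KO (y axis), both against WT normoxia, with genes also called between the SuHx groups in red. Cyp1a1 lies at 8.60 and -4.95, far from the dashed line of equal change.

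Isolated ECs were set against total lung, both of WT rats in normoxia, to find which genes are higher in the endothelium. Endothelial, immediate early and cytokine genes were higher in the ECs, and epithelial, fibroblast and red cell genes were lower. Leukocyte markers went both ways. Of the 20 tested endothelial cell markers, 18 were higher, 0 were lower and 2 were not called (adjusted over the list alone, 18 and 0), among them Mmrn2 (4.17-fold), the receptor kinase Tie1 (3.32-fold), Emcn (2.86-fold) and Car4 (2.84-fold). Endothelial markers passed as a list (median log2 fold change 1.51, adjusted p = 1.28e-08, and adjusted p = 0.269 with an estimated correlation). Of the 20 tested VEGF pathway and endothelial tip cell genes, 15 were higher, 3 were lower and 2 were not called (adjusted over the list alone, 15 and 3), with the receptors Flt4 (4.37-fold) and Flt1 (3.73-fold) higher and the pericyte ligand Angpt1 11.8-fold lower (list: median log2 fold change 1.14, adjusted p = 0.000822, and adjusted p = 0.269 with an estimated correlation). Of the 29 tested BMP signalling and pulmonary hypertension genes, 15 were higher, 7 were lower and 7 were not called (adjusted over the list alone, 16 and 7). Edn1 was 13.1-fold and the endothelin receptor Ednrb 3.82-fold higher, and Tbx4, a transcription factor of the lung mesenchyme, 8.99-fold lower (list: median log2 fold change 0.73, adjusted p = 0.0128, and adjusted p = 0.279 with an estimated correlation).

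Of the 18 tested immediate early and heat shock genes, 16 were higher, 0 were lower and 2 were not called (adjusted over the list alone, 16 and 0). The AP-1 subunit Fosb was at 72834 ± 26831 in the ECs against 112 ± 20.2 in lung (614-fold), Jun was 19.7-fold, Atf3 85.3-fold and Ier3 21.0-fold higher (list: median log2 fold change 4.34, adjusted p = 1.28e-08, and adjusted p = 0.238 with an estimated correlation). Of the 29 tested cytokines, chemokines and adhesion molecules, 24 were higher, 1 was lower and 4 were not called (adjusted over the list alone, 25 and 1), with Cxcl2 (323-fold), Il1a (32.7-fold), Ptgs2 (28.3-fold) and Cxcl1 (16.0-fold). The cytokine list passed too (median log2 fold change 3.91, adjusted p = 1.42e-09, and adjusted p = 0.269 with an estimated correlation). Of the 11 tested glucocorticoid-induced genes, 7 were higher, 0 were lower and 4 were not called (adjusted over the list alone, 7 and 0), with Mt2A (68.4-fold), Mt1 (29.5-fold), Cdkn1a (8.58-fold) and Sgk1 (5.12-fold). Glucocorticoid-induced genes passed as a list (median log2 fold change 1.97, adjusted p = 0.000822, and adjusted p = 0.429 with an estimated correlation). Of the 17 tested interferon-stimulated genes, 13 were higher, 0 were lower and 4 were not called (adjusted over the list alone, 13 and 0), with Rsad2 (5.82-fold) and Gbp2 (3.10-fold). Interferon-stimulated genes passed as a list (median log2 fold change 0.97, adjusted p = 0.000884, and adjusted p = 0.488 with an estimated correlation). Next to Fosb and Cxcl2, the largest differences upward were those of Fam71a (562-fold), the protease Adamts4 (459-fold), Fos (132-fold), the capillary gene Cd300lg (91.4-fold), Nr4a3 (76.2-fold), Egr1 (75.1-fold) and Il6 (71.7-fold).

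Leukocyte markers were among the genes higher in the ECs. Of the 13 tested neutrophil markers, 7 were higher, 0 were lower and 6 were not called (adjusted over the list alone, 7 and 0), with Il1r2 (20.8-fold) and S100a9 (4.35-fold). The neutrophil list did not pass (median log2 fold change 0.97, adjusted p = 0.0509, and adjusted p = 0.590 with an estimated correlation). T and NK cell markers gave 9 higher, 4 lower and 5 not called, or 10 and 4 adjusted over the list alone, with Ccr7 11.3-fold and Cd28 10.8-fold higher (list: median log2 fold change 1.30, adjusted p = 0.0509, and adjusted p = 0.771 with an estimated correlation). Monocyte and macrophage markers gave 2 higher, 6 lower and 8 not called, or 1 and 6 adjusted over the list alone, with Cd14 5.38-fold higher and C1qc 3.97-fold lower (list adjusted p = 0.406). Mast cell markers gave 3 higher, 0 lower and 5 not called, or 3 and 0 adjusted over the list alone, with Kit 2.23-fold higher (list adjusted p = 0.104), and extracellular matrix genes 7 higher, 15 lower and 5 not called, or 9 and 16 adjusted over the list alone (list adjusted p = 0.215).

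Most epithelial, fibroblast and red cell markers were lower in the ECs. All 16 alveolar epithelial markers were lower, also adjusted over the list alone, with Rtkn2 (6.31-fold) and Ager (4.47-fold). The alveolar list was lower (median log2 fold change -1.78, adjusted p = 0.000104, and adjusted p = 0.491 with an estimated correlation). Of the 15 tested airway epithelial markers, 0 were higher, 10 were lower and 5 were not called (adjusted over the list alone, 0 and 10), with the ciliated cell gene Foxj1 (37.3-fold) and Scgb1a1 (10.1-fold). The airway list was lower (median log2 fold change -1.88, adjusted p = 0.00317, and adjusted p = 0.397 with an estimated correlation). Of the 12 tested fibroblast markers, 2 were higher, 8 were lower and 2 were not called (adjusted over the list alone, 2 and 8), with Pdgfra (62.8-fold), Col13a1 (50.1-fold) and Tcf21 (32.9-fold lower; list: median log2 fold change -3.99, adjusted p = 0.0112, and adjusted p = 0.523 with an estimated correlation). Of the 14 tested smooth muscle and pericyte markers, 2 were higher, 10 were lower and 2 were not called (adjusted over the list alone, 2 and 10), with Cspg4 (3.10-fold) lower and Rgs5 (1.81-fold) higher (list: median log2 fold change -0.90, adjusted p = 0.0274, and adjusted p = 0.599 with an estimated correlation). Of the 9 tested erythroid cell markers, 0 were higher, 8 were lower and 1 was not called (adjusted over the list alone, 0 and 8), with Alas2 (44.9-fold) and Hbb (34.6-fold). The erythroid list was lower (median log2 fold change -4.98, adjusted p = 0.000893, and adjusted p = 0.491 with an estimated correlation). Of the 11 tested B and plasma cell markers, 8 were higher, 1 was lower and 2 were not called (adjusted over the list alone, 8 and 1): Pax5 (8.97-fold) was higher (list: median log2 fold change 1.71, adjusted p = 0.0115, and adjusted p = 0.590 with an estimated correlation). The largest differences downward were those of the chemokine Ccl11 (155-fold lower), Ccna1 (111-fold), Spata18 (111-fold), Slc7a10 (110.4-fold), Fbxo40 (106-fold), the cilium gene Sntn (103-fold), Ubxn10 (106-fold), the row of Calm3 and Gng8 (93.1-fold) and Adra1a (87.8-fold). Elmod1 was listed at 0 in the ECs and at 112, 72.4 and 93.6 in lung.

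AhR target genes differed both ways between ECs and lung, with 3 higher, 4 lower and 2 not called, or 3 and 4 adjusted over the list alone. Tiparp was 7.65-fold, Slc7a5 2.84-fold and Cyp1a1 9.35-fold higher, and Cyp1b1 (1.98-fold), Nqo1 (2.17-fold), Aldh3a1 (4.37-fold) and the Ugt1a6 row (2.47-fold) were lower. Ahr (log2 fold change 0.43 ± 0.21, adjusted p = 0.125), Ahrr (log2 fold change -0.46 ± 0.63, adjusted p = 0.570) and Xdh (log2 fold change 0.40 ± 0.17, adjusted p = 0.0850) were not called. That list did not pass (adjusted p = 0.956), and its median (-0.46) and mean (0.231) differed in sign. The other 11 lists did not pass either, while fry called 5 of them: the hypoxia-induced genes (adjusted p = 0.0152), NRF2 targets (0.00219), matrix genes (0.0155) and neutrophil and monocyte markers (0.0304 and 0.0465). Among these lists, for the cell cycle genes the median (-0.01) and the mean (-0.0465) had the opposite sign to the test. In this comparison limma called 8539 of 15186 genes, 3969 higher and 4570 lower, of which 1801 and 2608 differed at least 2-fold. None of the 13 list calls held with an estimated correlation, the BMP call was lost with quantile normalization (adjusted p = 0.197), and that setting turned the sign of 115 called genes. The day of the ECs is labelled 4 and that of the lungs 0, and isolation differs between the groups too.

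**Figure D5:**
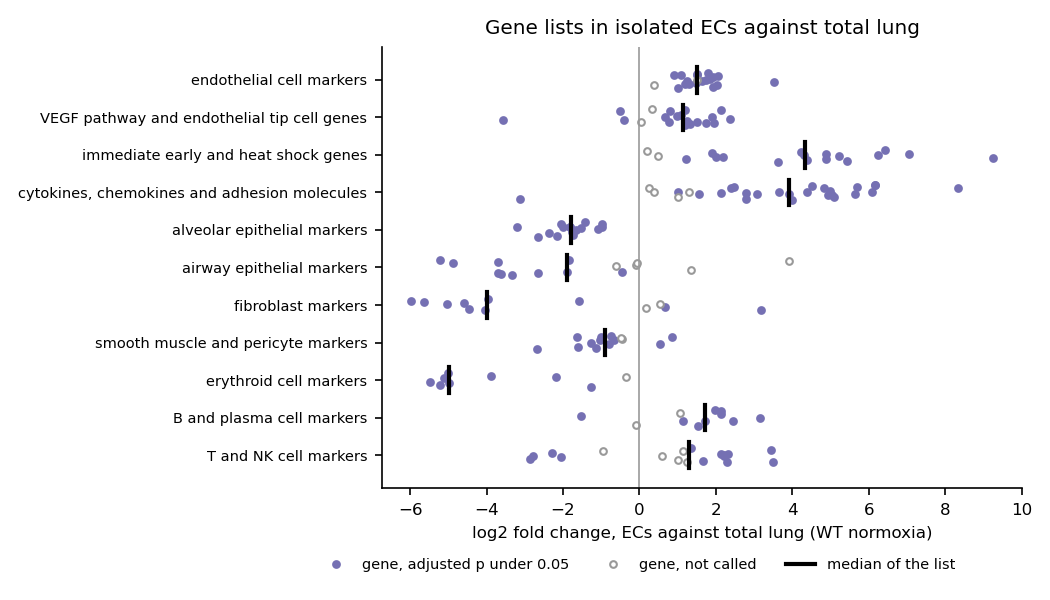
Log2 fold change of each tested member (points) of 11 gene lists in ECs against total lung, WT normoxia, n = 3 per group, with list medians (bars). The immediate early and heat shock genes have a median of 4.34 and the endothelial cell markers one of 1.51.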

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

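The 3 tests of the cardiac pattern, the test of neighbouring genes that respond together, and the fit with a cardiac score were chosen only after the results were seen.

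Cyp1a1 drew attention because its SuHx changes against the same normoxia libraries went opposite ways. Its log2 fold change was 8.60 in WT and -4.95 in the lungs labelled Ahr-KO. These differed by -13.55 ± 0.72 (limma's adjusted p = 2.08e-05) between the SuHx groups, with all 3 libraries labelled Ahr-KO below all WT ones. Nqo1 did so too, with 3.09 and -0.69, a difference of -3.78 ± 0.15 (adjusted p = 4.39e-06). Its fall in the lungs labelled Ahr-KO lost its call in 5 of 16 alternatives (adjusted p up to 0.123). The difference was tested only as a direct comparison of the SuHx groups, since the table holds no Ahr-KO normoxia group, so whether the genotypes differed before treatment was not tested. Ahr mRNA was not lower in the libraries labelled Ahr-KO (log2 fold change 0.03 ± 0.26, adjusted p = 0.966), so the genotype is given as labelled.

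For each of the 4 comparisons, 1 of the 10 splits of the 6 libraries gave as many genes, the real one. The real counts were 2052 for WT SuHx against normoxia (highest other split 1), 76 between the SuHx groups (highest other 2), 1485 for Ahr-KO SuHx against normoxia (highest other 0) and 8539 for ECs against lung (highest other 0). These splits are too few for a share under 0.05.

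Cardiac muscle markers were high in WT normoxia replicate 2 and in the 3 libraries labelled Ahr-KO. The normoxia library is labelled WT, so its high markers do not go with the labelled genotype. That all 14 tested markers reached the lowest library labelled Ahr-KO there restates the pattern and decides nothing. Cardiac tissue taken along with the lung is a candidate source there: 12 further cardiac muscle genes outside the list, 9 of them above 0 in every lung library, were 20.2-fold higher in the median than the mean of the other 2 normoxia libraries, with Mb at 765 against 1.59 and 0. Between the SuHx groups, 13 of 14 markers had all libraries labelled Ahr-KO above all WT libraries. Markers of 1 tissue can rise together, so these are not 14 independent observations. As a list they had an adjusted p of 0.871 in camera with an estimated correlation and of 0.286 in fry. A difference in dissection cannot be told apart from one of the labelled genotype there, because both would go with the group and no label gives a dissection batch.

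The 76 genes called between the SuHx groups could come from the labelled genotype itself, as the comparison was meant to show. Weighed beside it are that cardiac tissue, chromosome segments of another background carried with the Ahr-KO line, and neighbouring genes responding to SuHx together. A difference in preparation between the groups was not tested, since no label gives a preparation batch. For cardiac tissue as the whole cause, the signs named before the fit with the cardiac score as a covariate were met both ways, so they do not decide it. The log2 fold changes had a median ratio of 0.993 to those without the score (0.653 to 1.36), and a ratio over 0.8 had been named as counting against this cause. Of the 76 calls 14 were kept, and such a loss had been named as a sign for it. Over the 76 the median size was 1.31 before and 1.34 after, and the median standard error 0.170 and 0.245. All 62 lost calls had a larger standard error, 54 of them by a larger factor than the fold change fell (fold change as large or larger in 27, smaller in 35). The fold changes thus mostly stayed while their errors grew. The score was itself higher in all libraries labelled Ahr-KO than in all WT SuHx libraries, so the fit can part score and group only in part. Of the 100 tested genes nearest to Ahr in the GRCr8 assembly 1 (Mboat2) was called, while 0.499% of all tested genes were. This argues against a segment around Ahr itself with many called genes. A segment with few detectable differences would give the same count and is not excluded. Called genes lay within 5 tested genes of each other in 8 pairs, against a median of 2 in 10000 random sets (permutation p = 0.000700). Segments elsewhere in the genome could give such an excess, and so could related or jointly responding genes lying together, which random sets do not keep. Ahrr with Exoc3, Nqo1 with Pmfbp1 and Tiparp with Veph1 each held an AhR target, and Ms4a7 with Ms4a8 and Il1r1 with Il1r2 were related genes. The others were Cytl1 with Stk32b, Rarb with Lrrc3b and Nectin1 with Mfrp. Neighbours responding together stay open. Of the 8 pairs 6 changed one way in WT SuHx, against a median of 5 in 10000 shuffles of these calls (permutation p = 0.335).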

How the results depend on the processing

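The tests without the libraries rich in cardiac or airway RNA, with the cardiac score, and with isolated low values set to missing were chosen only after the results were seen. No gene called in the 4 comparisons was called in the opposite direction under any alternative run, and none of the named called genes reversed. Of these named genes, 64 of 84 (WT SuHx against normoxia), 11 of 28 (between the SuHx groups), 45 of 78 (Ahr-KO SuHx against normoxia) and 112 of 117 (ECs) kept their call under every alternative, the replicate block included. Quantile normalization turned the sign of 115 of the 8539 EC calls. The counts of called genes were 2052, 76, 1485 and 8539 as reported, and the alternatives not named here left them within 1.5 times. Depth was 20.04 M to 28.6 M reads per library, at which 67 of 100 genes changed 2-fold were called in the simulated WT SuHx comparison. Alternatives planned for whole counts were not run, since the values are scaled.

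With an absolute log2 fold change of at least 1, which by construction calls fewer genes, the counts were 748 (WT SuHx), 659 (Ahr-KO SuHx against normoxia) and 4409 (ECs). Shared calls were then 437 in place of 967 and opposite calls 32 in place of 52, and the median log2 fold changes in the lungs labelled Ahr-KO were 1.67 in place of 0.73 and -0.93 in place of -0.50. Without the trend, 47 genes were called between the SuHx groups and 31 in opposite directions. All 12 libraries in the fit gave 126 between the SuHx groups. The cardiac score as a covariate gave 19 there and 556 for Ahr-KO SuHx against normoxia. With an estimated correlation, 0 lists in place of 12 passed (WT SuHx), 1 in place of 5 (between the SuHx groups), 0 in place of 9 (Ahr-KO SuHx against normoxia) and 0 in place of 13 (ECs). With fry, 2 passed between the SuHx groups and 5 for Ahr-KO SuHx against normoxia. Apart from the fold change minimum, the cause was not tested.

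Leaving out 1 library gave 862–2277 genes for WT SuHx (953 and 1148 without normoxia 0 and 1, 862 and 1115 without WT SuHx 0 and 2). Between the SuHx groups it gave 32–55 (32, 39 and 39 without WT SuHx 0, 1 and 2, 37 and 35 without Ahr-KO 0 and 1). For Ahr-KO SuHx against normoxia it gave 721–1882 (795 and 888 without normoxia 0 and 1, 976, 721 and 875 without Ahr-KO 0, 1 and 2), and for ECs 7239–8069. List calls ranged over 10–13, 4–8 (8 without Ahr-KO 0), 8–13 and 13–17. Shared calls ranged over 536–1223 (541 and 594 without normoxia 0 and 1, 536 without WT SuHx 0, 542 without Ahr-KO 1). Opposite calls ranged over 22–57 (28 without normoxia 0, 22, 29 and 23 without WT SuHx 0, 1 and 2, 24 and 22 without Ahr-KO 0 and 1). The median log2 fold change in the lungs labelled Ahr-KO ranged from 0.61 to 1.34 over the genes that rose in WT (1.34 without normoxia 0, 1.32 without WT SuHx 0) and from -0.67 to -0.38 over those that fell. Beyond the smaller number of libraries, the cause was not tested.

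The suffixes 0 to 2 of the columns recur in every group, and no source ties them to an animal, a litter or a day. Libraries with the same suffix deviated from their group means with correlations across genes of -0.0384 to 0.0927 (WT SuHx against normoxia), -0.0138 to 0.196 (between the SuHx groups), 0.0840 to 0.215 (Ahr-KO SuHx against normoxia) and 0.00748 to 0.110 (ECs), so the suffix was not taken to pair them. Of the 6 libraries of each comparison, 4, 2, 6 and 4 correlated best with their own suffix, a hint from the data and not from the design. With the suffix as a replicate block the counts of called genes were 3385, 82, 2171 and 8559, with 3385 for WT SuHx over 1.5 times the 2052 reported; the cause was not tested. Shared calls were 1564 and opposite calls 56, and the median log2 fold changes in the lungs labelled Ahr-KO were 0.48 and -0.39. The block called 12, 6, 9 and 16 lists and lost none, the added ones being the airway markers between the SuHx groups (adjusted p = 0.0432) and the hypoxia-induced genes (0.0369), neutrophil markers (0.0339) and T and NK cell markers (0.00676) in ECs. Of the called genes named, 83 of 84, 23 of 28, 78 of 78 and 116 of 117 were called with the block, and 2 more were, Tef for Ahr-KO SuHx against normoxia (adjusted p = 0.0357) and Ahr in ECs (0.0480).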

Other observations

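Both tests of the EC pattern were chosen only after the result was seen, as were the genes named in the next paragraph.

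Genes outside the lists also differed between the SuHx groups. Efnb2, an ephrin ligand of arterial endothelium, had a mean signal of 6289 in normoxia, 1209.7 in WT SuHx and 2763 in the lungs labelled Ahr-KO (log2 fold change 1.16 ± 0.19, adjusted p = 0.0380 between the SuHx groups). The gap junction gene Gja4 had 1762, 1358 and 2596 (log2 fold change 0.93 ± 0.10, adjusted p = 0.00354), and the growth factor Pdgfd 366, 178 and 516 (log2 fold change 1.54 ± 0.15, adjusted p = 0.00178). Other endothelial genes were not called: the Notch target Hey1 (log2 fold change 1.19 ± 0.22, adjusted p = 0.0549), Gja5 (adjusted p = 0.647), Ephb4 (adjusted p = 0.895) and Nr2f2 (adjusted p = 0.811). Lower in the lungs labelled Ahr-KO were the IL-1 receptor Il1r1 (log2 fold change -0.99 ± 0.11, adjusted p = 0.00383) and the scavenging chemokine receptor Ackr3 (log2 fold change -1.32 ± 0.14, adjusted p = 0.00368). So were the retinoic acid receptor Rarb (log2 fold change -1.23 ± 0.17, adjusted p = 0.0184), the glutathione transferase Gstp1 (log2 fold change -1.82 ± 0.22, adjusted p = 0.00758) and Nfe2l2, the gene of NRF2 (log2 fold change -0.84 ± 0.11, adjusted p = 0.0103).

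Between ECs and lung, hypoxia-induced genes gave 13 higher, 5 lower and 8 not called, or 15 and 5 adjusted over the list alone and did not pass as a list (adjusted p = 0.0509), with the histone demethylase Kdm3a 2.43-fold and the glucose transporter Slc2a1 2.07-fold higher and the mitophagy gene Bnip3l 1.67-fold lower.

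Immediate early and heat shock genes were higher in the ECs by a median log2 fold change of 4.34. Enrichment of endothelial cells alone is argued against, since this lies above the largest value of any endothelial marker (3.53, Prox1) and above their median of 1.51. A response to isolating the cells and a difference of the cells in the animal cannot be told apart, because all ECs were isolated and no lung was. That 16 of 18 members had all ECs above all normoxia lungs restates the difference and decides nothing.

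In Ahr-KO replicate 2 the mitochondrial rows COX1, CYTB, ND5, ND6 and the merged row of ATP6 and its neighbours were listed at 0, while ND1 was at 61147 and ND2 at 63433. COX1 lay between 88219.7 and 147125 in the other lung libraries. Mitochondrial rows took 0.606% of the signal in that library and 1.77% to 2.72% in the other 11. ND5 was at 0.000159 in WT SuHx replicate 2. Such isolated low values numbered 9, of which 6 lay in Ahr-KO replicate 2. With them set to missing, the 4 comparisons gave 2070, 76, 1499 and 8541 calls. Rows low in more than 1 library of a group, such as Igip in WT SuHx, are not among these isolated values.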
